A study of Homo sapiens with 8 samples.

How the data were processed

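Gene expression was measured by RNA sequencing of total RNA from the lymphoma lines Karpas-231 and SC1, grown with 20% serum and treated for 24 h with DMSO or with chidamide at a dose the labels write as 0.5 mm. RNA was extracted with Trizol, and libraries were made with standard Illumina protocols, per the labels' protocols. The deposited table holds expected counts per gene symbol as whole numbers, 1 column for each of the 8 libraries, with no scaling between libraries. Per the submitters' processing notes, fastp, STAR, RSEM and the genome build GRCh38 were used, with no version, setting or role stated. The gene annotation, the strand setting and the rounding are not stated. Overlapping genes, paralogs and processed pseudogenes may therefore share counts, histone, HLA and ribosomal protein genes among them.

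The table had 58684 gene rows, of which 27468 had a count in any library. Of these rows 28 had symbols that look like dates, as spreadsheet software makes of some gene names, and were left under the symbols given, and 2 symbols were used by more than 1 row. Positions, gene types, GC content and transcript lengths came from GENCODE release 29 on GRCh38, matched by symbol, with 36996 symbols matched directly, 29 through an older symbol, 52 to several genes and 21607 not at all. Coordinates are those of this annotation, since the table gives none. GC content was available for 13476 of the 16190 tested genes (83.2%). Levels of sex-linked marker genes were not examined.

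Libraries were grouped by the line and the letter C or T of their titles, with C read as DMSO and T as chidamide, into 4 groups of 2. No batch, date or lane is given in the labels. Replicates of a group were not copies of each other, with chi-square per degree of freedom from 10.3 to 28.6.

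Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which left 16190, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 8 libraries with robust dispersion, and 4 contrasts were tested, T against C in each line, the difference of these between the lines, and SC1 C against Karpas-231 C. P-values were adjusted by the Benjamini-Hochberg method over all tested genes within a contrast, and genes with an adjusted p below 0.05 were called, two-sided. The p-values unadjusted were below 0.05 for 8060 genes in Karpas-231, 4922 in SC1, 4676 for the difference and 8973 between the C libraries. The biological coefficient of variation was 15.4%. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM are counts scaled to the TMM-adjusted library size, and their SD is over 2 libraries. With 2 libraries per group no rank or permutation test of a single gene can reach 0.05, so tests rest on the spread shared across genes and groups.

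There were 38 gene lists, of which 31 pathway and complex lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with estimated correlations and with fry from limma 3.58.1 as alternatives. Camera compares a list with all other genes, while fry asks whether the members move on balance 1 way. The adjusted p of the 31 lists is over all 31 of a contrast. No call of camera held with an estimated correlation, where the adjusted p of the called lists ran from 0.33 to 0.84 in Karpas-231, 0.263 to 0.427 in SC1 and 0.545 to 0.728 for the difference. Lists were written from general knowledge and not from these libraries. The remaining lists hold markers of other cell types and mitochondrially encoded genes, and were used as levels.

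Genes were named by a rule. It took a panel of 23 genes in every comparison, the 8 largest rises and 8 largest falls per line and the 6 largest differences each way between lines among called genes with a mean of at least 10 CPM and no overlap of the groups, and the 3 members with the smallest adjusted p of each called list. Clone names, pseudogenes, immunoglobulin and T cell receptor segments and sex-linked markers were passed over in the ranking. The other genes named, TRBC2, PECAM1 and LYZ, the members of the check list that were called, list members that went against their list, and the examples of the closing section, were chosen after their values were seen. A fold against a group with no count is given as a lower bound, computed against 3 counts in each library. Of the panel and the lists, 1 gene and 1 list are not reported here.

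The groups, the tests, the lists, the rule for named genes and most of the alternatives were set before the data were examined. These alternatives were scaling by median of ratios or by library totals alone, DESeq2 1.42.0, no low-count filter, a filter at 5 CPM in 2 libraries, a fit of only the libraries compared, a block for the replicate number, an adjusted p below 0.01, estimated correlations, fry, and leaving out each library in turn. After seeing the data 4 alternatives were added, an offset for GC content (lowess span 0.3, from genes with a mean of at least 20 counts), an offset for GC content and transcript length, genes with a GC value, and protein-coding genes. Where a group is left with 1 library, that library is assumed to vary like the other groups.

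The scripts were tested on simulated data drawn from the real means and library sizes. In a simulated T against C comparison of Karpas-231 with 15695 genes tested, 46 of 99 genes changed by 2-fold and 9 of 97 changed by 1.5-fold were called, with 10 false calls. In SC1, with 15694 genes tested, the numbers were 45 of 99 and 20 of 97, with 11 false calls. The test of the difference between lines called 18 and 21 of the 99 2-fold changes. With a simulated GC tilt in Karpas-231 (13210 genes), false calls were 2921 without and 10 with the offset. In a simulated SC1 list test camera called the shifted list (adjusted p = 2.96e-35) and 0 of 30 others. Such draws link no genes, so specificity for correlated lists was not tested. A 2-fold change may thus be missed, as most smaller ones were, and a gene not called was not shown to be unchanged.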

Results

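RNA sequencing counts were examined for 8 libraries of 2 human cell lines of B-cell lymphoma, a tumour of B lymphocytes, Karpas-231 and SC1. Each line was given DMSO, the solvent control, or chidamide, an oral inhibitor of histone deacetylases, for 24 h. Chidamide acts on HDAC1, HDAC2, HDAC3 and HDAC10. The sample titles give only the letters C and T, which are read here as control and treated. The labels write the dose as 0.5 mm, a unit that can be read in more than 1 way. Each of the 4 groups, Karpas-231 C, Karpas-231 T, SC1 C and SC1 T, held 2 libraries. Nothing in the labels says that the 2 replicates of a group came from separate cultures, so they may be technical replicates. The study's title sets CREBBP, a histone acetyltransferase, and the cell cycle machinery beside the sensitivity of relapsed or refractory lymphoma to the drug. Expression is given as CPM (counts scaled to the library size), mean ± SD with n = 2 libraries per group. Log2 fold changes are given ± SE. List members counted are those tested, and settings are alternative ways of processing.

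Library totals were 28544140 and 28011847 counts in Karpas-231 C, 20548560 and 18314850 in Karpas-231 T, 23039401 and 20735327 in SC1 C, and 20428428 and 16783105 in SC1 T. A floor of 3 counts per library corresponds to 0.105 to 0.179 CPM across these libraries, and covers counting error only. More genes had a count in the T libraries than in the C libraries of the same line, 20846 and 20970 against 19622 and 19724 in Karpas-231 and 20884 and 21224 against 19963 and 19977 in SC1. Mitochondrially encoded genes took 0.534% and 0.526% of counts in Karpas-231 C, 0.591% and 0.608% in Karpas-231 T, 0.699% and 0.777% in SC1 C, and 0.955% and 0.933% in SC1 T. Principal component 1 held 64.8% of the variance and parted the lines, and component 2 held 20.7% and parted T from C.

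**Figure D1:**
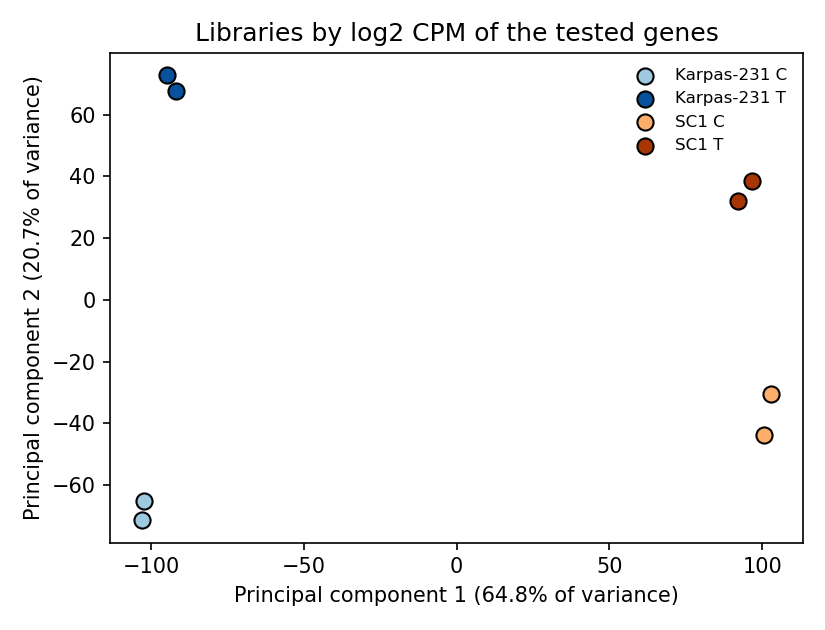
Each point is 1 of the 8 libraries, placed by its log2 CPM over the 16190 tested genes, with component 1 (64.8% of variance) on the horizontal axis and component 2 (20.7% of variance) on the vertical axis. Colours give the 4 groups of 2 libraries, and the replicates of a group lie next to each other.

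Some markers of other cell types moved with treatment. Myeloid markers summed to 1.30 and 1.68 CPM in Karpas-231 C and to 21.1 and 24.7 CPM in Karpas-231 T, where LYZ, the lysozyme gene, rose from 0.868 ± 0.345 to 11.7 ± 1.26 CPM (log2 fold change 3.74 ± 0.45, adjusted p = 1.26e-05). In SC1 they summed to 0.434 and 0.627 CPM in C and to 2.99 and 2.15 CPM in T. Fibroblast and endothelial markers summed to 5.68 and 6.78 CPM in Karpas-231 C and 35.3 and 42.6 CPM in T. The rise was chiefly in PECAM1, an adhesion molecule of endothelial and blood cells (6.72 ± 0.891 to 35.6 ± 2.49 CPM). In SC1 the sum was 0.347 and 0.434 CPM in C and 6.32 and 6.91 CPM in T. PECAM1 rose from 0.314 ± 0.0817 to 5.84 ± 0.384 CPM. T cell markers summed to 208 and 186 CPM in Karpas-231 C and 74.1 and 61.5 CPM in T. TRBC2, a T cell receptor segment, made up most of this sum in C. It fell from 191 ± 18.7 to 17.8 ± 0.872 CPM (log2 fold change -3.43 ± 0.15, adjusted p = 5.21e-09). In SC1 the sum was 78.6 and 75.9 CPM in C and 84.1 and 62.3 CPM in T. TRBC2 fell from 56.2 ± 3.92 to 25.8 ± 4.01 CPM. Of 11 tested markers only TRBC2 fell, while CD4 and LCK rose in Karpas-231 and LCK and TRAC in SC1.

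Genes known to respond to histone deacetylase inhibition were examined first, as a check of the letters C and T. CDKN1A, which encodes the cell cycle inhibitor p21 (chromosome 6, 36676460 to 36687339, GRCh38), rose in both lines. In Karpas-231 it went from 23.2 and 18.5 CPM in C to 56.7 and 60.8 CPM in T (log2 fold change 1.49 ± 0.41, adjusted p = 0.0259). In SC1 it went from 43.2 and 18.3 CPM to 106 and 72.3 CPM (log2 fold change 1.53 ± 0.40, adjusted p = 0.0475). The call in Karpas-231 was lost in 4 of 19 settings (adjusted p from 9.73e-08 to 0.117, 0.0779 without Karpas-231 C replicate 1, 0.117 without Karpas-231 C replicate 2, 0.052 without SC1 T replicate 1 and 0.0532 without SC1 T replicate 2). The call in SC1 was lost in 6 of 19 settings (adjusted p from 1.15e-07 to 0.207, 0.08 without Karpas-231 C replicate 1, 0.0788 without Karpas-231 C replicate 2, 0.0515 without Karpas-231 T replicate 1, 0.0505 without Karpas-231 T replicate 2, 0.207 without SC1 T replicate 1 and 0.102 without SC1 T replicate 2). H1F0, a linker histone gene often used as a marker of such drugs, had 8 counts in Karpas-231 C replicate 1 and 0 in the other 7 libraries, too few to be tested. In the list of genes induced by histone deacetylase inhibitors, 6 of 18 members rose in SC1, 0 fell and 12 were not called (camera adjusted p = 0.0115, adjusted p = 0.397 with an estimated correlation). 8 rose and 0 fell adjusted over the list alone. The members that rose in SC1 were CDKN1A, GADD45A, GSN, SYT11, HSPA2 and CPT1C. The list call in SC1 was lost in 3 of 17 settings (adjusted p from 0.00107 to 0.295, 0.0702 without SC1 C replicate 2 and 0.295 without SC1 T replicate 1). In Karpas-231 the list was not called: 3 of 18 members rose, 6 fell and 9 were not called (camera adjusted p = 0.19, adjusted p = 0.748 with an estimated correlation). 3 rose and 6 fell adjusted over the list alone. CDKN1A, DHRS2 and SYT11 rose there, and TUBB3, HIST1H2BC, HIST1H2BK, HIST1H2AC, CTSD and HSPA2 fell. HSPA2, a testis-enriched heat shock protein, went in opposite directions, from 1.20 ± 0.291 to 0.157 ± 0.152 CPM in Karpas-231 and from 0.200 ± 0.0196 to 1.78 ± 0.0701 CPM in SC1 (adjusted p = 0.000824 for the difference). Calls lost in some settings were, in Karpas-231, those of DHRS2 (adjusted p from 4.87e-16 to 0.131), SYT11 (adjusted p from 1.44e-06 to 0.161, 0.0785 without Karpas-231 C replicate 1, 0.0631 without Karpas-231 C replicate 2, 0.0973 without Karpas-231 T replicate 2), HIST1H2BC (adjusted p from 0.000104 to 0.0899, 0.0899 without Karpas-231 C replicate 1), CTSD (adjusted p from 0.000175 to 0.265, 0.0714 without Karpas-231 T replicate 2) and HSPA2 (adjusted p from 0.00117 to 0.0617, 0.0617 without Karpas-231 T replicate 1). In SC1 they were those of GADD45A (adjusted p from 0.00714 to 0.256, 0.0658 without Karpas-231 C replicate 1, 0.0683 without Karpas-231 C replicate 2, 0.0665 without Karpas-231 T replicate 1, 0.064 without Karpas-231 T replicate 2, 0.256 without SC1 C replicate 2, 0.191 without SC1 T replicate 1), GSN (adjusted p from 0.0164 to 0.118, 0.118 without SC1 C replicate 1, 0.0743 without SC1 C replicate 2, 0.0922 without SC1 T replicate 2) and CPT1C (adjusted p from 0.0187 to 0.237, 0.0593 without Karpas-231 C replicate 1, 0.0587 without Karpas-231 C replicate 2, 0.066 without Karpas-231 T replicate 1, 0.0664 without Karpas-231 T replicate 2, 0.0586 without SC1 C replicate 1, 0.237 without SC1 C replicate 2, 0.188 without SC1 T replicate 1, 0.0753 without SC1 T replicate 2). The check list therefore moved as the letters imply in SC1 and not in Karpas-231, while CDKN1A did so in both lines.

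In Karpas-231, T against C asks which genes the drug changed in this line. Lists of cell cycle, MYC target and histone genes were called lower in the T libraries, and those of MHC class II presentation and cytokine receptor signalling higher (n = 2 libraries per group). All lost their call with an estimated correlation (adjusted p from 0.33 to 0.62). CDK4, the kinase that drives entry into the cell cycle (chromosome 12, 57747727 to 57756013, GRCh38), fell from 217 ± 2.81 to 84.4 ± 8.51 CPM (log2 fold change -1.36 ± 0.12, adjusted p = 1.15e-06). E2F1, a transcription factor of the same step (chromosome 20, 33675683 to 33686404, GRCh38), fell from 89.6 ± 1.63 to 31.6 ± 2.88 CPM (log2 fold change -1.50 ± 0.15, adjusted p = 2.00e-06). HLA-DQA1, a chain of an MHC class II molecule, rose from 10.1 ± 0.541 to 90.0 ± 9.91 CPM (log2 fold change 3.16 ± 0.21, adjusted p = 1.21e-07). BCL6, the repressor that maintains the germinal centre state (chromosome 3, 187721377 to 187745727, GRCh38), fell from 78.1 ± 2.50 to 43.6 ± 0.828 CPM (log2 fold change -0.84 ± 0.12, adjusted p = 7.24e-05), and PRDM1, the regulator of plasma cell differentiation, rose from 1.16 ± 0.265 to 8.96 ± 2.66 CPM (log2 fold change 2.94 ± 0.38, adjusted p = 2.44e-05).

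The 8 largest rises among well expressed genes were those of HMCN1, ADAM28, C10orf128, DPP4, TEX19, RHOBTB3, FNBP1 and IL6ST. HMCN1, an extracellular matrix protein, rose from 0.237 ± 0.170 to 24.2 ± 8.86 CPM (log2 fold change 6.64 ± 0.48, adjusted p = 1.91e-07). ADAM28, a metalloprotease of lymphocytes, rose from 1.99 ± 1.05 to 86.1 ± 2.43 CPM (log2 fold change 5.43 ± 0.36, adjusted p = 7.52e-07). The 8 largest falls were those of PNMAL1, IGLL1, ZNF544, SH2D4B, HIST2H3D, RGS19, HIST1H3J and NUDT16L1. IGLL1, a surrogate light chain of immature B cells, fell from 356 ± 85.9 to 15.8 ± 0.782 CPM (log2 fold change -4.49 ± 0.20, adjusted p = 5.81e-09). HIST2H3D and HIST1H3J, both histone H3 genes, fell from 113 ± 3.70 to 9.89 ± 1.94 CPM and from 68.4 ± 2.34 to 6.79 ± 0.858 CPM. C10orf128 rose from 0.709 ± 0.0646 to 23.4 ± 1.23 CPM and PNMAL1 fell from 22.8 ± 2.04 to 0.433 ± 0.0883 CPM, and neither had a count in any SC1 library.

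Cell cycle lists were called lower. In the G1/S list, 32 of 64 members fell, 2 rose and 30 were not called (camera adjusted p = 1.26e-05, adjusted p = 0.62 with an estimated correlation). 32 fell and 2 rose adjusted over the list alone. E2F2 fell from 213 ± 36.8 to 57.5 ± 5.78 CPM and UHRF1, which maintains DNA methylation at replication, fell from 878 ± 72.4 to 335 ± 43.4 CPM. In the G2/M list, 46 of 74 members fell, 1 rose and 27 were not called (camera adjusted p = 9.14e-10, adjusted p = 0.33 with an estimated correlation). 50 fell and 2 rose adjusted over the list alone. CDC25B, a phosphatase that activates mitotic kinases, fell from 222 ± 41.0 to 65.3 ± 4.15 CPM, and the mitotic kinase gene PLK1 fell from 137 ± 5.02 to 56.8 ± 0.365 CPM. Among cyclins and cyclin-dependent kinases, 14 of 23 members fell, 2 rose and 7 were not called (camera adjusted p = 2.69e-06, adjusted p = 0.33 with an estimated correlation). 15 fell and 2 rose adjusted over the list alone. CCND3, a D-type cyclin, fell from 89.8 ± 16 to 23.7 ± 0.308 CPM (log2 fold change -1.92 ± 0.16, adjusted p = 5.89e-07). CDK6, a kinase related to CDK4, rose from 203 ± 25.0 to 339 ± 12.9 CPM, a call lost in 1 of 19 settings (adjusted p from 1.50e-08 to 0.0835). That setting was the GC and length offset, where its log2 fold change was 0.29 against 0.74. Among MYC target genes, 43 of 55 members fell, 0 rose and 12 were not called (camera adjusted p = 1.26e-15, adjusted p = 0.35 with an estimated correlation). 46 fell and 0 rose adjusted over the list alone. BOP1, a factor of ribosome assembly, fell from 123 ± 13.1 to 26.9 ± 4.36 CPM, and CAD, an enzyme of pyrimidine synthesis, fell from 277 ± 33.3 to 92.5 ± 5.89 CPM. MYC itself was called lower, from 349.7 ± 36.2 to 267 ± 13.9 CPM (log2 fold change -0.39 ± 0.15, adjusted p = 0.0465), but this call was lost in 12 of 19 settings (adjusted p from 0.00345 to 0.463, 0.463 without Karpas-231 C replicate 1, 0.118 without Karpas-231 C replicate 2, 0.191 without Karpas-231 T replicate 1 and 0.368 without Karpas-231 T replicate 2).

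Lists of histone and acetyltransferase genes were lower too, while the lists of histone methylation genes and of histone deacetylases were not called (adjusted p = 0.424 and 0.0827), the latter called by fry alone (0.0048). In the list of linker and replication-independent histone genes, 11 of 17 members fell, 0 rose and 6 were not called (camera adjusted p = 4.11e-05, adjusted p = 0.35 with an estimated correlation). 12 fell and 0 rose adjusted over the list alone. H2AFX, the variant histone phosphorylated at DNA breaks, fell from 257 ± 16.7 to 47.1 ± 10.3 CPM (log2 fold change -2.45 ± 0.15, adjusted p = 6.37e-08). Many histone genes are close paralogs, so counts may be shared among them. Many of their mRNAs lack poly(A), and small RNA took 2.21% and 1.90% of counts in Karpas-231 C, 0.702% and 1.68% in Karpas-231 T, 0.722% and 1.13% in SC1 C, and 1.10% and 0.822% in SC1 T. Among histone acetyltransferases and their partners, 14 of 25 members fell, 1 rose and 10 were not called (camera adjusted p = 0.00195, adjusted p = 0.33 with an estimated correlation). 14 fell and 1 rose adjusted over the list alone. KAT5 and ING5, of acetyltransferase complexes, fell from 59.4 ± 1.15 to 26.9 ± 0.0960 CPM and from 77.6 ± 4.73 to 33.1 ± 1.39 CPM. CREBBP stood at 39.4 ± 6.88 CPM in C and 37.3 ± 2.09 CPM in T (adjusted p = 0.72), and EP300 at 75.9 ± 9.93 and 63.3 ± 3.84 CPM (adjusted p = 0.141). Among cytoplasmic ribosomal protein genes, 25 of 65 members fell, 7 rose and 33 were not called (camera adjusted p = 0.0159, adjusted p = 0.84 with an estimated correlation). 25 fell and 8 rose adjusted over the list alone. This call was lost in 4 of 17 settings (adjusted p from 0.00238 to 0.273, 0.273 without Karpas-231 T replicate 2) and by fry (0.252), and with library totals alone (0.0672). RPLP2 fell from 616 ± 58.4 to 178 ± 5.44 CPM and RPL13 fell from 1373 ± 49.0 to 484 ± 53.6 CPM, genes with many processed pseudogenes.

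Some immune lists rose, while those of MHC class I, B cell receptor signalling and NF-kB were not called (adjusted p = 0.126, 0.839 and 0.537). In the MHC class II list, 14 of 22 members rose, 2 fell and 6 were not called (camera adjusted p = 4.90e-05, adjusted p = 0.62 with an estimated correlation). 14 rose and 2 fell adjusted over the list alone. HLA-DMB, which helps load peptides, rose from 72.5 ± 0.453 to 163 ± 17.9 CPM, while CD74, the invariant chain, and RFXANK were the members that fell. HLA genes are similar and highly variable in sequence, so reads may be assigned unevenly among them. In the JAK-STAT and cytokine receptor list, 17 of 31 members rose, 2 fell and 12 were not called (camera adjusted p = 2.14e-05, adjusted p = 0.553 with an estimated correlation). 19 rose and 2 fell adjusted over the list alone. IL6ST, the signalling subunit shared by interleukin 6 family receptors, rose from 2.25 ± 0.640 to 32.6 ± 0.798 CPM (log2 fold change 3.86 ± 0.23, adjusted p = 3.67e-08). In the interferon response list, 18 of 45 members rose, 5 fell and 22 were not called (camera adjusted p = 0.00793, adjusted p = 0.748 with an estimated correlation). 18 rose and 5 fell adjusted over the list alone. PARP14 rose from 49.5 ± 3.05 to 173 ± 13.2 CPM and EPSTI1 rose from 0.533 ± 0.201 to 9.22 ± 1.77 CPM, and the list call was lost in 1 of 17 settings (adjusted p from 0.00131 to 0.0617, 0.0617 without Karpas-231 T replicate 2) and by fry (0.099). In the plasma cell list, 9 of 29 members rose, 1 fell and 19 were not called (camera adjusted p = 0.0316, adjusted p = 0.35 with an estimated correlation). 7 rose and 1 fell adjusted over the list alone. Beside PRDM1, CAV1, the coat protein of caveolae, rose from 5.94 ± 0.0747 to 48.7 ± 0.882 CPM, and MZB1 was the member that fell. The plasma cell call was lost in 1 of 17 settings (adjusted p from 0.00754 to 0.058, 0.058 without Karpas-231 C replicate 2).

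The neuronal list was called higher and lists of energy metabolism lower. In the neuronal list, 8 of 18 members rose, 1 fell and 9 were not called (camera adjusted p = 0.0122, adjusted p = 0.33 with an estimated correlation). 8 rose and 1 fell adjusted over the list alone. MAP2, a microtubule protein of dendrites, rose from 4.71 ± 1.42 to 41.5 ± 6.92 CPM (log2 fold change 3.14 ± 0.23, adjusted p = 3.63e-07), and the list call was lost in 2 of 17 settings (adjusted p from 0.00261 to 0.172, 0.067 without Karpas-231 C replicate 2). Among glycolysis genes, 15 of 25 members fell, 7 rose and 3 were not called (camera adjusted p = 0.0159, adjusted p = 0.62 with an estimated correlation). 15 fell and 7 rose adjusted over the list alone. ALDOA fell from 826 ± 51.4 to 268 ± 3.91 CPM and LDHA fell from 2313 ± 10.5 to 1012 ± 97.4 CPM, and the list call was lost in 5 of 17 settings (adjusted p from 0.00707 to 0.143, 0.0622 without Karpas-231 T replicate 2). The 7 glycolysis members that rose were SLC2A3, HK1, PFKFB4, ALDOC, ENO2, LDHB and PDK1. Among oxidative phosphorylation genes, 20 of 48 members fell, 3 rose and 25 were not called (camera adjusted p = 0.000473, adjusted p = 0.748 with an estimated correlation). 22 fell and 3 rose adjusted over the list alone. NDUFS8, a subunit of complex I, fell from 54.1 ± 4.75 to 13.6 ± 1.28 CPM, and CYC1, a cytochrome of complex III, fell from 209 ± 10.3 to 67.1 ± 2.05 CPM. By fry the list was not called (adjusted p = 0.0992).

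Of the panel of 23 genes set before the values were seen, 22 were tested in Karpas-231, and 5 rose, 7 fell and 10 were not called, the drug targets HDAC2 and HDAC3 among them. Besides CDKN1A, CDK6 and PRDM1, HDAC1 rose from 207 ± 8.61 to 272 ± 28.1 CPM and CCND2 rose from 0.0979 ± 0.0823 to 0.882 ± 0.547 CPM. Besides BCL6, CCND3, CDK4, E2F1 and MYC, HDAC10 fell from 2.59 ± 0.914 to 0.743 ± 0.0707 CPM and MCL1, an inhibitor of apoptosis, fell from 331 ± 16.4 to 255 ± 18.7 CPM. Calls of 7 of these 12 genes did not hold throughout, those of CDKN1A, CDK6 and MYC given above among them. HDAC1 was lost in 3 of 19 settings (adjusted p from 0.00132 to 0.0905, 0.08 without Karpas-231 C replicate 1 and 0.0876 without Karpas-231 T replicate 1). CCND2 was lost in 5 of 18 settings (adjusted p from 0.00534 to 0.275, 0.0672 without Karpas-231 C replicate 1, 0.179 without Karpas-231 C replicate 2, 0.0546 without Karpas-231 T replicate 1 and 0.275 without Karpas-231 T replicate 2). HDAC10 was lost in 5 of 18 settings (adjusted p from 0.00268 to 0.325, 0.186 without Karpas-231 C replicate 1, 0.154 without Karpas-231 T replicate 1 and 0.119 without Karpas-231 T replicate 2). MCL1 was lost in 10 of 19 settings (adjusted p from 0.0022 to 0.347, 0.32 without Karpas-231 C replicate 1, 0.149 without Karpas-231 C replicate 2, 0.11 without Karpas-231 T replicate 1 and 0.347 without Karpas-231 T replicate 2).

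In all, edgeR called 3372 genes higher and 3448 lower in Karpas-231 T among 16190 tested, of which 2157 were at least 2-fold higher and 1528 at least 2-fold lower. Camera called 14 of the 31 tested lists, 5 higher and 9 lower. With an estimated correlation it called 0, fry called 11 of the 14, and 9 of the 14 were called with each of the 8 libraries left out in turn. The genes called lower numbered 2062 and 2259 without C replicate 1 and C replicate 2, and 2124 and 2108 without T replicate 1 and T replicate 2. Scaling by library totals alone, which moved the median log2 fold change to 0.19, put 62.8% of the called genes higher against 49.4%. Fold changes fell with the GC content of the gene, from a median of 0.27 in the lowest of 10 equal groups of genes to -0.82 in the highest, and over the 13476 genes with a GC value 877 were at least 2-fold lower with a GC offset, added after seeing the data, against 1398 without.

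**Figure D2:**
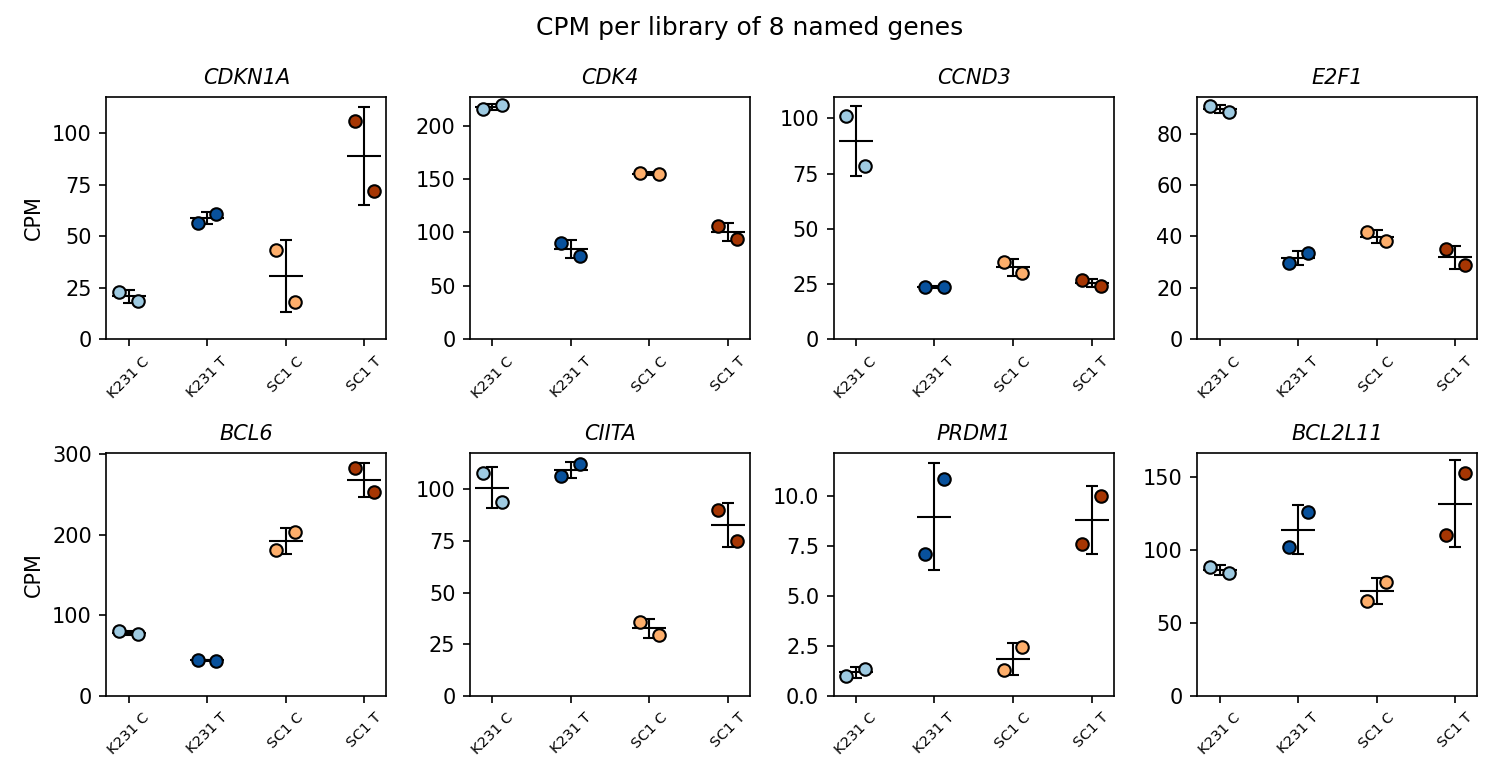
Each panel shows 1 gene, with the CPM of every library as a point over the 4 groups and the mean as a dash with its SD (n = 2) as whiskers, on linear axes that start at 0. CDKN1A and PRDM1 are higher in T than in C in both lines, CDK4 is lower in both, and BCL6 is lower in Karpas-231 T and higher in SC1 T.

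**Figure D3:**
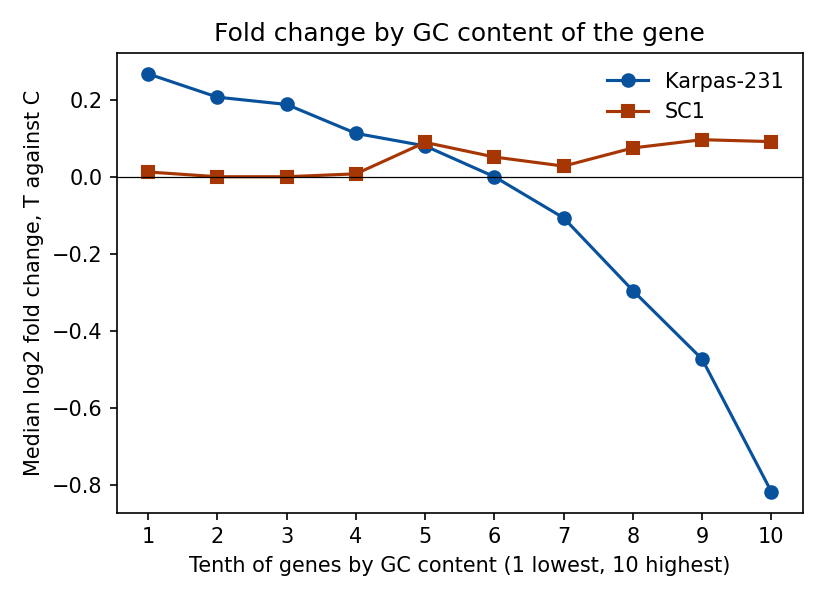
The median log2 fold change of T against C (vertical axis) is drawn for 10 equal groups of genes by GC content, from lowest to highest (horizontal axis), with circles for Karpas-231 and squares for SC1. In Karpas-231 it runs from 0.27 to -0.82, and in SC1 from 0.01 to 0.09.

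In SC1, T against C asks the same question in the other line. Lists of B cell receptor, MHC presentation and interferon response genes were called higher in the T libraries, and those of cell cycle, MYC target and oxidative phosphorylation genes lower (n = 2 libraries per group). All lost their call with an estimated correlation (adjusted p from 0.302 to 0.397). CIITA, the master regulator of MHC class II genes, rose from 32.6 ± 4.70 to 82.6 ± 10.7 CPM (log2 fold change 1.34 ± 0.15, adjusted p = 2.61e-05). PRDM1 rose from 1.85 ± 0.803 to 8.79 ± 1.71 CPM (log2 fold change 2.25 ± 0.37, adjusted p = 0.000761). CDK4 fell from 155 ± 1.07 to 100.1 ± 8.51 CPM (log2 fold change -0.63 ± 0.12, adjusted p = 0.00266). FCGR2B, an inhibitory Fc receptor of B cells, rose from 0.270 ± 0.0791 to 19.4 ± 4.14 CPM (log2 fold change 6.15 ± 0.40, adjusted p = 1.04e-06).

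The 8 largest rises among well expressed genes were those of ERBB3, PRKCB, SMIM14, CD180, ATP6V0A1, HVCN1, RCAN3 and CD48. PRKCB, the protein kinase C that acts below the B cell receptor, rose from 1.10 ± 0.312 to 20.8 ± 0.263 CPM (log2 fold change 4.22 ± 0.20, adjusted p = 1.33e-08). ERBB3, of the epidermal growth factor receptor family, rose from 1.25 ± 1.25 to 24.9 ± 4.13 CPM (log2 fold change 4.28 ± 0.64, adjusted p = 0.00259). CD180, a surface receptor of B cells, rose from 3.51 ± 1.81 to 42.1 ± 6.67 CPM. The 8 largest falls were smaller and were those of CYB5D1, CNTN5, RPP40, KLF15, KCTD15, BTBD3, IFT172 and EBNA1BP2. CNTN5, a neural adhesion molecule, fell from 116 ± 16.6 to 42.1 ± 2.80 CPM (log2 fold change -1.46 ± 0.16, adjusted p = 5.23e-05). EBNA1BP2, a factor of ribosome assembly, fell from 162 ± 30.3 to 71.5 ± 1.87 CPM. The call of KLF15 was lost in 3 of 19 settings (adjusted p from 4.38e-05 to 0.269, 0.269 without SC1 C replicate 1 and 0.152 without SC1 T replicate 2).

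B cell lists were called higher. In the B cell receptor signalling list, 17 of 43 members rose, 2 fell and 24 were not called (camera adjusted p = 4.71e-09, adjusted p = 0.302 with an estimated correlation). 18 rose and 2 fell adjusted over the list alone. PTPN6, the phosphatase SHP-1, rose from 0.840 ± 0.202 to 12 ± 1.67 CPM (log2 fold change 3.82 ± 0.31, adjusted p = 2.23e-06). In the germinal centre list, 13 of 34 members rose, 2 fell and 19 were not called (camera adjusted p = 0.000372, adjusted p = 0.397 with an estimated correlation). 15 rose and 3 fell adjusted over the list alone. S1PR2, a receptor that keeps B cells in germinal centres, rose from 1.41 ± 0.483 to 8.77 ± 2.19 CPM. BCL6 rose from 192 ± 15.8 to 268 ± 21.4 CPM (log2 fold change 0.48 ± 0.12, adjusted p = 0.0122), a call lost in 3 of 19 settings (adjusted p from 0.00307 to 0.0843, 0.0843 without SC1 C replicate 1 and 0.0591 without SC1 T replicate 1). Among genes that CREBBP and BCL6 regulate in opposite ways, 17 of 35 members rose, 1 fell and 17 were not called (camera adjusted p = 9.27e-11, adjusted p = 0.302 with an estimated correlation). 22 rose and 2 fell adjusted over the list alone. In the plasma cell list, 8 of 29 members rose, 2 fell and 19 were not called (camera adjusted p = 0.0469, adjusted p = 0.306 with an estimated correlation). 9 rose and 2 fell adjusted over the list alone. CD38 rose from 82.0 ± 17.2 to 145 ± 5.81 CPM and CAV1 rose from 0.974 ± 0.194 to 9.35 ± 1.29 CPM, and the list call was lost in 12 of 17 settings (adjusted p from 0.0124 to 0.235, 0.0703 without Karpas-231 C replicate 1, 0.0668 without Karpas-231 C replicate 2, 0.103 without Karpas-231 T replicate 1, 0.114 without Karpas-231 T replicate 2, 0.0802 without SC1 C replicate 2 and 0.235 without SC1 T replicate 1). SEC11C and TXNDC5, of the secretory pathway, were the plasma cell members that fell.

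Lists of antigen presentation and of inflammatory signalling were called higher. In the MHC class II list, 17 of 22 members rose, 0 fell and 5 were not called (camera adjusted p = 3.08e-11, adjusted p = 0.302 with an estimated correlation). 17 rose and 0 fell adjusted over the list alone. In the MHC class I list, 8 of 21 members rose, 0 fell and 13 were not called (camera adjusted p = 0.000683, adjusted p = 0.335 with an estimated correlation). 11 rose and 0 fell adjusted over the list alone. HLA-B rose from 29.8 ± 8.58 to 81.2 ± 21.9 CPM. In the interferon response list, 29 of 45 members rose, 0 fell and 16 were not called (camera adjusted p = 1.28e-17, adjusted p = 0.302 with an estimated correlation). 35 rose and 0 fell adjusted over the list alone. IRF1 rose from 8.05 ± 1.79 to 21.5 ± 2.34 CPM (log2 fold change 1.41 ± 0.17, adjusted p = 7.82e-05), and EPSTI1 rose from 3.33 ± 0.966 to 20.6 ± 2.88 CPM. In the NF-kB target list, 12 of 28 members rose, 0 fell and 16 were not called (camera adjusted p = 3.04e-07, adjusted p = 0.306 with an estimated correlation). 13 rose and 0 fell adjusted over the list alone. In the JAK-STAT and cytokine receptor list, 15 of 31 members rose, 0 fell and 16 were not called (camera adjusted p = 3.22e-08, adjusted p = 0.302 with an estimated correlation). 16 rose and 0 fell adjusted over the list alone. IL4R rose from 3.70 ± 1.29 to 16.4 ± 3.71 CPM and STAT3 rose from 15.7 ± 2.09 to 33.5 ± 0.925 CPM. In the neuronal list, 8 of 18 members rose, 0 fell and 10 were not called (camera adjusted p = 2.31e-05, adjusted p = 0.263 with an estimated correlation). 9 rose and 0 fell adjusted over the list alone. MAP2 rose from 15.6 ± 4.26 to 107 ± 1.27 CPM and SYT11 rose from 0.561 ± 0.596 to 13.4 ± 0.442 CPM.

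Cell cycle and growth lists were called lower in SC1 as well. In the G1/S list, 20 of 64 members fell, 0 rose and 44 were not called (camera adjusted p = 1.84e-10, adjusted p = 0.302 with an estimated correlation). 29 fell and 0 rose adjusted over the list alone. MCM7, a subunit of the replicative helicase, fell from 869 ± 34.9 to 553 ± 98.4 CPM. In the G2/M list, 13 of 74 members fell, 0 rose and 61 were not called (camera adjusted p = 5.02e-07, adjusted p = 0.302 with an estimated correlation). 13 fell and 0 rose adjusted over the list alone. CCNA2, cyclin A, fell from 517 ± 10.1 to 312 ± 11.5 CPM (log2 fold change -0.73 ± 0.12, adjusted p = 0.000635). Among cyclins and cyclin-dependent kinases, 4 of 23 members fell, 1 rose and 18 were not called (camera adjusted p = 0.000405, adjusted p = 0.302 with an estimated correlation). 8 fell and 1 rose adjusted over the list alone. CDK6 was the member that rose, from 296 ± 40.4 to 479.8 ± 95.8 CPM, a call lost in 1 of 19 settings (adjusted p from 6.31e-05 to 0.0509, 0.0509 without SC1 C replicate 2). Among MYC target genes, 24 of 55 members fell, 0 rose and 31 were not called (camera adjusted p = 2.35e-14, adjusted p = 0.302 with an estimated correlation). 33 fell and 0 rose adjusted over the list alone. LYAR fell from 160.4 ± 38.0 to 83.6 ± 12.7 CPM, and MYC fell from 138 ± 27.5 to 95.6 ± 13.9 CPM (log2 fold change -0.53 ± 0.15, adjusted p = 0.0252), a call lost in 3 of 19 settings (adjusted p from 0.000166 to 0.236, 0.236 without SC1 C replicate 2 and 0.145 without SC1 T replicate 2).

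Repair, metabolic and chromatin genes made up other called lists. Among genes of DNA double-strand break repair, 8 of 46 members fell, 0 rose and 38 were not called (camera adjusted p = 0.00126, adjusted p = 0.397 with an estimated correlation). 8 fell and 0 rose adjusted over the list alone. BRCA1 fell from 265 ± 20.3 to 183 ± 5.25 CPM, and the list was not called by fry (adjusted p = 0.0538). Among oxidative phosphorylation genes, 15 of 48 members fell, 0 rose and 33 were not called (camera adjusted p = 1.34e-09, adjusted p = 0.397 with an estimated correlation). 18 fell and 0 rose adjusted over the list alone. This list too was not called by fry (adjusted p = 0.0851). CYC1 fell from 102 ± 2.95 to 57.0 ± 16.2 CPM. Among glycolysis genes, 6 of 25 members fell, 3 rose and 16 were not called (camera adjusted p = 0.0238, adjusted p = 0.41 with an estimated correlation). 6 fell and 4 rose adjusted over the list alone. HK2 fell from 98.8 ± 18.6 to 55.4 ± 4.56 CPM, and the list call was lost in 3 of 17 settings (adjusted p from 0.00178 to 0.189, 0.189 without SC1 T replicate 2) and by fry (0.132). In the unfolded protein and amino acid response list, 5 of 31 members fell, 0 rose and 26 were not called (camera adjusted p = 0.00373, adjusted p = 0.426 with an estimated correlation). 5 fell and 0 rose adjusted over the list alone. This call was lost in 1 of 17 settings (adjusted p from 2.54e-13 to 0.838, 0.838 without SC1 C replicate 1) and by fry (0.285), with the direction turned without that library. Among histone acetyltransferases and their partners, 6 of 25 members fell, 3 rose and 16 were not called (camera adjusted p = 0.0195, adjusted p = 0.302 with an estimated correlation). 7 fell and 3 rose adjusted over the list alone. KAT5 fell from 45.1 ± 0.924 to 28.6 ± 2.13 CPM, and the list call was lost in 2 of 17 settings (adjusted p from 0.000745 to 0.105, 0.055 without SC1 T replicate 1). CREBBP stood at 38.5 ± 2.89 CPM in C and 38.8 ± 2.93 CPM in T (adjusted p = 0.99). In the list of histone methylation and chromatin genes of lymphoma, 8 of 35 members rose, 0 fell and 27 were not called (camera adjusted p = 0.0401, adjusted p = 0.422 with an estimated correlation). 10 rose and 1 fell adjusted over the list alone. BCOR, a corepressor, rose from 92.0 ± 12.2 to 163 ± 1.35 CPM, and the list call was lost in 12 of 17 settings (adjusted p from 0.00821 to 0.256, 0.0801 without Karpas-231 C replicate 1, 0.0798 without Karpas-231 C replicate 2, 0.065 without Karpas-231 T replicate 1, 0.0651 without Karpas-231 T replicate 2, 0.093 without SC1 C replicate 1 and 0.19 without SC1 T replicate 2).

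Of the 22 tested panel genes, 6 rose in SC1, 2 fell and 14 were not called. BCL2L11, the pro-apoptotic BIM gene, rose from 71.5 ± 8.95 to 132 ± 29.9 CPM (log2 fold change 0.88 ± 0.16, adjusted p = 0.00201) beside BCL6, CDK6, CDKN1A, CIITA and PRDM1, and CDK4 and MYC fell. In all, edgeR called 1835 genes higher and 945 lower in SC1 T among 16190 tested, of which 1294 were at least 2-fold higher and 39 at least 2-fold lower. Camera called 22 of the 31 tested lists, 13 higher and 9 lower. With an estimated correlation it called 0, fry called 17 of the 22, and 15 of the 22 were called with each of the 8 libraries left out in turn. Without SC1 C replicate 2 the calls were 1108 higher, 567 lower and 830 at least 2-fold higher. The 39 genes at least 2-fold lower numbered 63 without SC1 C replicate 1, 64 without SC1 C replicate 2 and 109 without SC1 T replicate 1. A fit of the 4 SC1 libraries alone called 1112 genes higher and 331 lower. With library totals alone 76.8% of the called genes were higher against 66.0%, the median log2 fold change being 0.12.

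**Figure D4:**
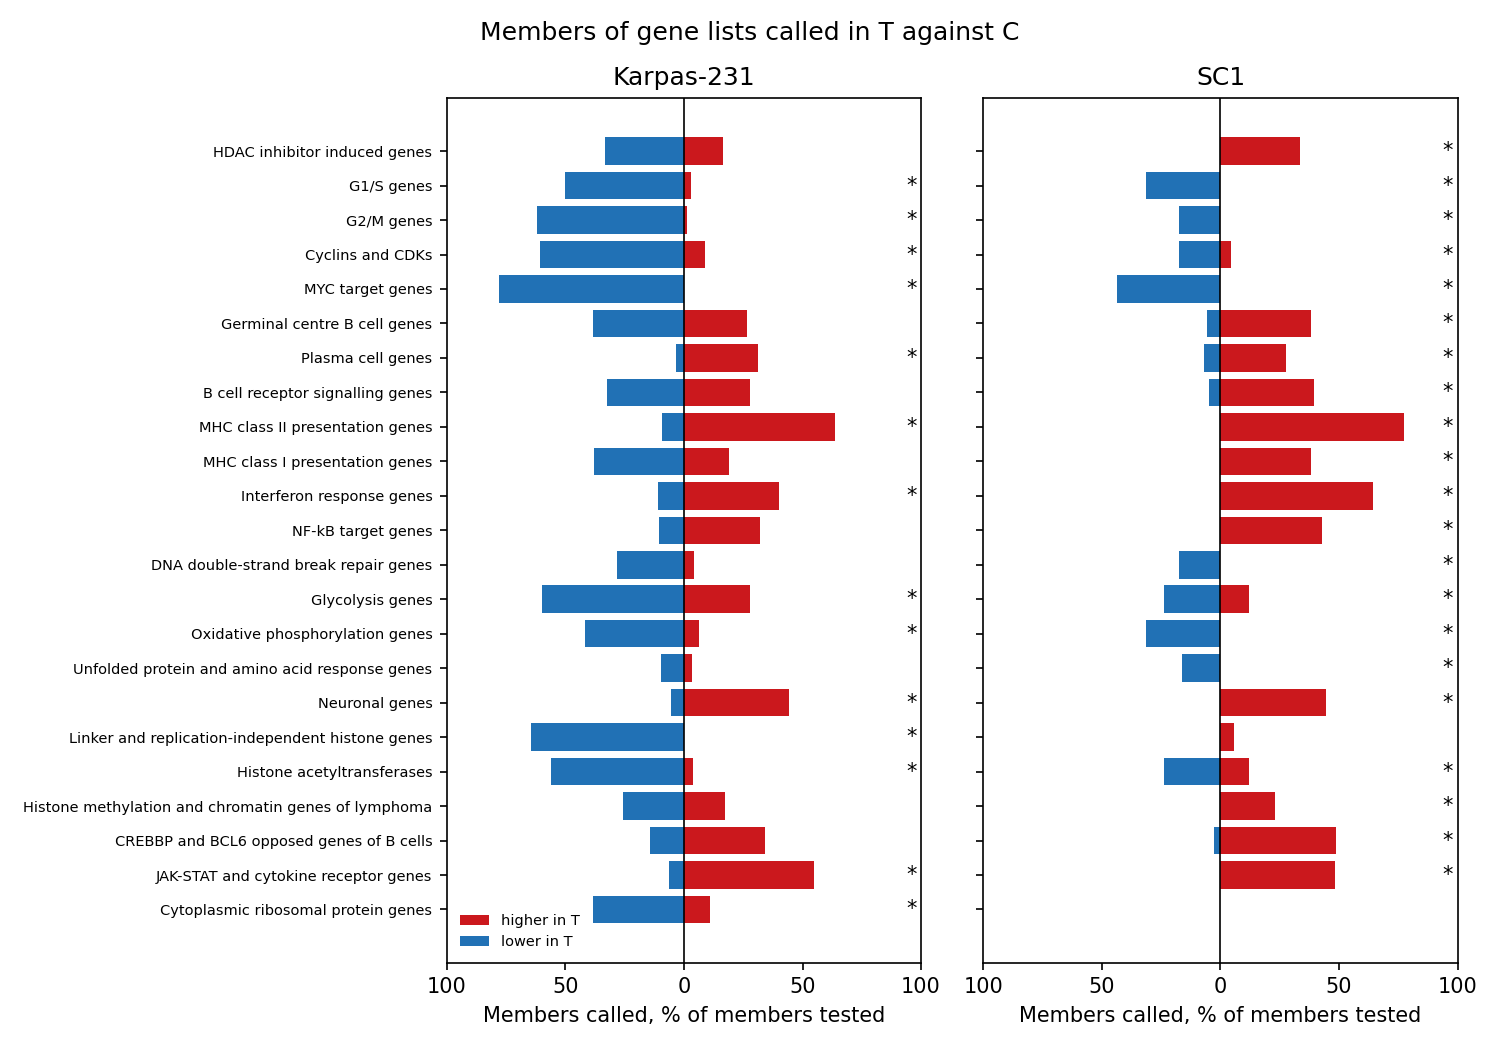
Bars give, for lists called in either line, the percent of tested members called higher in T (to the right) and lower in T (to the left), for Karpas-231 and SC1. A star marks a list called by camera in that line, 14 lists in Karpas-231 and 22 in SC1, 1 of the latter not drawn. The bars are counts of members and carry no error.

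The responses of the lines were then set against each other. The lines shared 1103 genes that rose in both, where chance gives 382, and 573 that fell in both, where chance gives 201. Only 28 genes rose in Karpas-231 and fell in SC1 (chance 197), and 74 fell in Karpas-231 and rose in SC1 (chance 391). Across the 16190 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.42 and Spearman's rho of 0.46. Among the 1778 genes called in both lines r was 0.73, and 94.3% had the same sign. The count of genes that fell in both was 327 and 311 without Karpas-231 C replicate 1 and C replicate 2, 306 without Karpas-231 T replicate 2 and 319 without SC1 C replicate 2.

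**Figure D5:**
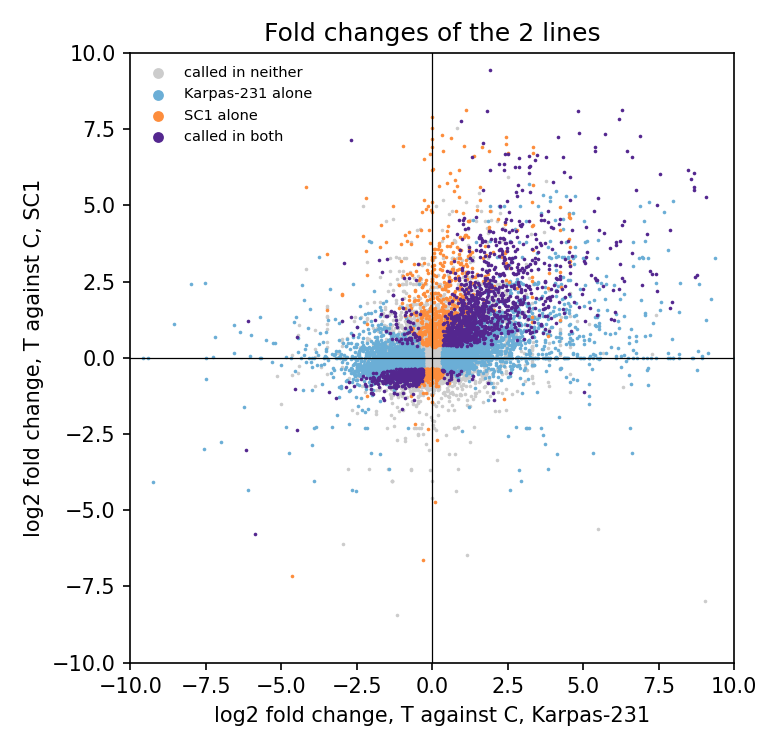
Each point is 1 tested gene, with its log2 fold change of T against C in Karpas-231 on the horizontal axis and in SC1 on the vertical axis. Colours mark genes called in both lines, in 1 line or in neither, and the axes stop at 10, which leaves out 6 genes. Points called in both lie mostly in the upper right and lower left (r of 0.73, 94.3% of the same sign).

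Some cell cycle and B cell genes responded differently in the lines by the test of the difference itself. BCL6 fell in Karpas-231 and rose in SC1 (difference on the log2 scale 1.32 ± 0.17, adjusted p = 0.000171). CIITA rose in SC1 and stood at 100.9 ± 9.84 and 109 ± 4.04 CPM in Karpas-231 (difference 1.23 ± 0.20, adjusted p = 0.000954). CCND3 fell in Karpas-231 and stood at 32.6 ± 3.72 and 25.5 ± 1.85 CPM in SC1 (difference 1.57 ± 0.22, adjusted p = 0.000328). E2F1 fell more in Karpas-231 than in SC1, where it was not called (difference 1.18 ± 0.20, adjusted p = 0.00131), a call lost in 2 of 18 settings (adjusted p from 4.84e-05 to 0.101), both with GC offsets. CDK4 fell in both lines and more in Karpas-231 (difference 0.73 ± 0.17, adjusted p = 0.00966), a call lost in 3 of 18 settings (adjusted p from 0.00164 to 0.114, 0.0921 without Karpas-231 C replicate 1, 0.0925 without Karpas-231 C replicate 2 and 0.114 without Karpas-231 T replicate 2).

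The largest differences among well expressed genes lay in genes near 0 in 1 group. AGGF1, an angiogenic factor, stood at 10.2 ± 3.07 CPM in Karpas-231 C and 0.0512 ± 0.00238 in Karpas-231 T, against 115 ± 19.4 and 114 ± 8.67 CPM in SC1 (adjusted p = 1.34e-06). DOCK8, a regulator of lymphocyte migration, stood at 0.0855 ± 0.121 and 3.41 ± 0.342 CPM in SC1, against 200.4 ± 6.39 and 164 ± 9.06 CPM in Karpas-231 (adjusted p = 6.20e-06). MACC1 had no count in SC1 C and rose at least 29.8-fold to 3.99 ± 1.12 CPM in SC1 T, and FAM49A likewise rose at least 11.4-fold to 1.53 ± 0.673 CPM, against a floor of 3 counts per library. In Karpas-231, ARHGAP21, FGF14 and DCBLD2 had no count in C and rose at least 6.81-fold, 5.23-fold and 3.23-fold, while CXADR was at least 1.67-fold lower in T, where it had no count. The remaining genes named by the rule were NCKAP1, at 0.0214 ± 0.0302 and 1.39 ± 0.233 CPM in SC1, and ACPP, CSTA and CCDC110, at 0.0585 ± 0.0828 and 2.51 ± 0.261, 0.0784 ± 0.0547 and 5.55 ± 1.13, and 0.0195 ± 0.0276 and 1.62 ± 0.503 CPM in Karpas-231 C and T. The call of the difference for CXADR was lost in 3 of 18 settings (adjusted p from 0.000466 to 0.0676, 0.0532 without Karpas-231 C replicate 2, 0.0676 without Karpas-231 T replicate 1 and 0.051 without Karpas-231 T replicate 2).

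As lists, 12 of the 31 had higher responses in SC1 than in Karpas-231. Lists not called include those of G1/S, MHC class II, JAK-STAT, plasma cell, histone acetyltransferase and histone deacetylase genes (adjusted p = 0.712, 0.969, 0.969, 0.393, 0.0949 and 0.239). The acetyltransferase list was called with the replicate block (0.0374), without SC1 T replicate 1 (0.0267) and by fry (0.0409), and the deacetylase list by fry (0.0409). Each count that follows gives members whose log2 fold change, with its sign, was higher or lower in SC1. In the B cell receptor signalling list, 18 of 43 members were higher, 2 were lower and 23 were not called (camera adjusted p = 5.05e-06, adjusted p = 0.545 with an estimated correlation). 20 were higher and 2 were lower adjusted over the list alone. In the germinal centre list, 13 of 34 members were higher, 1 was lower and 20 were not called (camera adjusted p = 5.05e-06, adjusted p = 0.545 with an estimated correlation). 17 were higher and 1 was lower adjusted over the list alone. The germinal centre list was not called by fry (adjusted p = 0.0511). In the list of linker and replication-independent histone genes, 6 of 17 members were higher, 0 were lower and 11 were not called (camera adjusted p = 5.05e-06, adjusted p = 0.545 with an estimated correlation). 9 were higher and 0 were lower adjusted over the list alone. For MHC class I presentation, 9 of 21 members were higher, 1 was lower and 11 were not called (camera adjusted p = 3.44e-05, adjusted p = 0.545 with an estimated correlation). 11 were higher and 1 was lower adjusted over the list alone. For the interferon response, 17 of 45 members were higher, 1 was lower and 27 were not called (camera adjusted p = 3.44e-05, adjusted p = 0.694 with an estimated correlation). 21 were higher and 1 was lower adjusted over the list alone. By fry this list was not called (adjusted p = 0.103). Among genes induced by histone deacetylase inhibitors, 4 of 18 members were higher, 0 were lower and 14 were not called (camera adjusted p = 0.000202, adjusted p = 0.545 with an estimated correlation). 6 were higher and 0 were lower adjusted over the list alone. Among cyclins and cyclin-dependent kinases, 7 of 23 members were higher, 0 were lower and 16 were not called (camera adjusted p = 0.00287, adjusted p = 0.545 with an estimated correlation). 7 were higher and 0 were lower adjusted over the list alone.

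The other 5 called lists lost their call with at least 1 library left out. For G2/M genes, 21 of 74 members were higher, 1 was lower and 52 were not called (camera adjusted p = 0.00149, adjusted p = 0.545 with an estimated correlation). 24 were higher and 2 were lower adjusted over the list alone. The call for G2/M was lost in 1 of 17 settings (adjusted p from 5.29e-07 to 0.0532, 0.0532 without Karpas-231 C replicate 1). For MYC target genes, 17 of 55 members were higher, 1 was lower and 37 were not called (camera adjusted p = 0.000544, adjusted p = 0.728 with an estimated correlation). 18 were higher and 1 was lower adjusted over the list alone. The MYC target call was lost in 1 of 17 settings (adjusted p from 2.08e-08 to 0.0666, 0.0666 without SC1 C replicate 1) and by fry (0.135). For NF-kB target genes, 6 of 28 members were higher, 0 were lower and 22 were not called (camera adjusted p = 0.016, adjusted p = 0.728 with an estimated correlation). 6 were higher and 0 were lower adjusted over the list alone. The NF-kB call was lost in 4 of 17 settings (adjusted p from 0.000719 to 0.282, 0.282 without SC1 C replicate 2 and 0.0714 without SC1 T replicate 1) and by fry (0.153). For histone methylation and chromatin genes of lymphoma, 12 of 35 members were higher, 0 were lower and 23 were not called (camera adjusted p = 0.00799, adjusted p = 0.545 with an estimated correlation). 12 were higher and 0 were lower adjusted over the list alone. The histone methylation call was lost in 3 of 17 settings (adjusted p from 0.000471 to 0.0918, 0.0529 without Karpas-231 C replicate 1). For genes that CREBBP and BCL6 regulate in opposite ways, 9 of 35 members were higher, 2 were lower and 24 were not called (camera adjusted p = 0.00431, adjusted p = 0.694 with an estimated correlation). 12 were higher and 2 were lower adjusted over the list alone. This last call was lost in 1 of 17 settings (adjusted p from 0.00011 to 0.089, 0.089 without SC1 C replicate 2) and by fry (0.111).

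In all, the log2 fold change, with its sign, was higher in SC1 for 1758 genes and lower for 828 of the 16190 tested. A higher or lower response has this signed meaning throughout. Of the 5042 genes called in Karpas-231 alone, 1848 differed between the lines by this test, and of the 1002 called in SC1 alone, 274 did. Of the 1676 genes called in both lines in the same direction, 292 differed. Camera called 12 lists, with 0 called with an estimated correlation, 7 by fry, and 7 called with each library left out in turn. The 1758 genes numbered 680 and 917 without Karpas-231 C replicate 1 and C replicate 2, and 636 and 916 without Karpas-231 T replicate 1 and T replicate 2. The 828 genes numbered 482 without Karpas-231 C replicate 1 and 482 without Karpas-231 T replicate 1, and scaling by library totals alone put 55.0% of the called genes higher in SC1 against 68.0%.

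The C libraries show how the lines differed before treatment. KIDINS220, CNTN5, PKP4, HIST3H2BB, PROX1 and BTBD3 had no count in Karpas-231 C and were well expressed in SC1 C, and PTK2, TGFBR2, PLD4, TES, GTSF1 and FAM49A showed the opposite. KIDINS220, a kinase substrate of neurons, stood at 156 ± 18.1 CPM in SC1 C (n = 2), at least 1320-fold higher by the floor of 3 counts per library. CNTN5, PKP4 and HIST3H2BB were at least 984-fold, 947-fold and 906-fold higher, and PROX1 and BTBD3 at least 722-fold and 413-fold higher. PTK2, the focal adhesion kinase, stood at 109 ± 1.27 CPM in Karpas-231 C and was at least 816-fold lower in SC1 C. TGFBR2, a receptor of transforming growth factor beta, was at least 574-fold lower, and PLD4, TES, GTSF1 and FAM49A at least 390.1-fold, 286-fold, 249.7-fold and 204-fold lower.

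Among the panel genes, BCL2, the anti-apoptotic gene often activated in lymphoma, stood at 349.5 ± 8.86 CPM in Karpas-231 C and 2344 ± 325 CPM in SC1 C (log2 difference 2.75 ± 0.15, adjusted p = 7.17e-10). BCL6 was higher in SC1 C, at 192 ± 15.8 against 78.1 ± 2.50 CPM (adjusted p = 4.20e-07). MYC was lower in SC1 C, at 138 ± 27.5 against 349.7 ± 36.2 CPM (adjusted p = 3.30e-06), as were CDKN1B, CIITA and E2F1, with log2 differences of -2.05 ± 0.24, -1.63 ± 0.15 and -1.17 ± 0.14. In all, 3554 genes were higher and 4487 lower in SC1 C than in Karpas-231 C among 16190 tested. With library totals alone 56.1% of the called genes were higher against 44.2%.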

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

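The tests of a difference between lines were set before the data were examined, while every test of an explanation in this part was chosen after the result was seen. Genes and lists are given here because their change with treatment differed between SC1 and Karpas-231 by the interaction test, edgeR for genes and camera for lists (n = 2 libraries per group). In brackets is the log2 difference, SC1 minus Karpas-231, and then the adjusted p, or the adjusted p alone where a group had too few counts for a fold. CXCR5, IGHG1, PECAM1, TRBC2, TUBA1B, TUBB and TUBB3 were chosen after their values were seen. Genes that fell in Karpas-231 and were not called in SC1 were ZNF544 (3.85, 2.87e-07), SH2D4B (0.00779), HIST2H3D (3.81, 0.000278), RGS19 (2.86, 6.98e-06), HIST1H3J (3.45, 1.14e-05), NUDT16L1 (2.66, 0.000797), CCND3 (1.57, 0.000328), E2F1 (1.18, 0.00131) and E2F2 (1.52, 0.000142). Further such genes were UHRF1 (1.18, 0.000695), CDC25B (1.44, 0.000973), PLK1 (1.04, 0.00173), BOP1 (1.81, 0.00038), CAD (1.42, 0.000237), NDUFS8 (1.65, 0.000766), H2AFX (2.59, 4.07e-06), RPLP2 (1.69, 4.49e-05) and RPL13 (1.48, 0.000765). The same held for AGGF1 (1.34e-06), CXADR (0.00817), TUBB3 (2.32, 0.000691), HIST1H2BK (1.70, 0.0088), TUBB (1.31, 0.000264), TUBA1B (0.98, 0.00206) and IGHG1 (2.06, 2.82e-05). Rises in both lines that differed in size were those of ADAM28 (-2.88, 0.00498), DPP4 (-2.35, 0.0265), RHOBTB3 (-1.23, 0.0226), FNBP1 (-2.94, 0.000118), IL6ST (-2.97, 1.75e-05), HLA-DQA1 (-1.62, 0.0012), EPSTI1 (-1.47, 0.0417), JAK2 (-1.77, 0.00166) and IFNGR1 (-0.60, 0.0411). Further such genes were PRKCB (3.15, 2.84e-06), SMIM14 (2.31, 0.000207), ATP6V0A1 (2.07, 0.000135), HVCN1 (1.77, 0.0114), RCAN3 (1.37, 0.0208), SYT11 (3.53, 0.000814), ZMAT3 (-0.92, 0.00858), MYBL1 (0.89, 0.0176) and FCGR2B (3.77, 0.00038). The same held for PTPN6 (2.08, 0.00236), MACC1 (0.000237), FAM49A (0.00328), CCDC110 (0.00112), PECAM1 (1.79, 0.00823) and CXCR5 (-1.19, 0.0365). Genes that rose in SC1 and were not called in Karpas-231 were CD180 (3.50, 0.000197), CD48 (2.55, 0.0265), CIITA (1.23, 0.000954), BTG2 (0.80, 0.0145), CD38 (0.74, 0.0257), IFI30 (1.56, 0.000861), PSMB9 (1.68, 0.000826), IRF1 (1.29, 0.0017) and CCR7 (3.42, 0.000274). Further such genes were DNMT3A (2.09, 0.000814), BCOR (0.83, 0.0077), ZEB2 (2.40, 2.11e-05), STAT3 (0.72, 0.0344), DOCK8 (6.19e-06) and NCKAP1 (0.000469). Falls in both lines that differed in size were those of IGLL1 (2.13, 0.000328), CDK4 (0.73, 0.00966), LDHA (0.60, 0.0382), ALDOA (1.13, 0.0015), CYC1 (0.80, 0.0229), MCM7 (0.62, 0.0398) and TRBC2 (2.30, 8.24e-06). Genes that rose in Karpas-231 and were not called in SC1 were HMCN1 (-6.39, 2.40e-05), ARHGAP21 (0.00193), FGF14 (0.00307), DCBLD2 (0.00213), ACPP (0.00391) and CSTA (0.000954). Genes that fell in Karpas-231 and rose in SC1 were BCL6 (1.32, 0.000171), S1PR2 (3.58, 9.67e-06), HLA-B (2.14, 0.000455) and HSPA2 (0.000824). Of these 81 differences 56 were called in every setting that tested them and 25 were lost in some. In brackets are the settings that ended the call and the highest adjusted p. Lost were MCM7 (11, 0.359), STAT3 (9, 0.229), IFNGR1 (9, 0.429), LDHA (8, 0.256), EPSTI1 (8, 0.184), CYC1 (7, 0.763), CD38 (7, 0.214), DPP4 (7, 0.203) and RHOBTB3 (6, 0.283). Lost too were RCAN3 (6, 0.12), CXCR5 (5, 0.126), MYBL1 (5, 0.152), BTG2 (4, 0.179), CD48 (4, 0.0963), HIST1H2BK (3, 0.0525), CXADR (3, 0.0676) and CDK4 (3, 0.114), and BCOR (3, 0.14), PECAM1 (2, 0.0671), E2F1 (2, 0.101), HVCN1 (2, 0.0716), SH2D4B (1, 0.327), ADAM28 (1, 0.0607), ZMAT3 (1, 0.0537) and TUBA1B (1, 0.0575). With the GC offset 74 were kept, while RHOBTB3 (0.0848), E2F1 (0.101), EPSTI1 (0.121), IFNGR1 (0.419), CYC1 (0.62), MCM7 (0.359) and ZMAT3 (0.0537) were lost.

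The lists that differed, each with a higher response in SC1, were HDAC inhibitor induced genes (0.000202), G2/M genes (0.00149), cyclins and CDKs (0.00287), MYC target genes (0.000544), germinal centre B cell genes (5.05e-06), B cell receptor signalling genes (5.05e-06), MHC class I presentation genes (3.44e-05), interferon response genes (3.44e-05), NF-kB target genes (0.016), linker and replication-independent histone genes (5.05e-06), histone methylation and chromatin genes of lymphoma (0.00799) and CREBBP and BCL6 opposed genes of B cells (0.00431). With an estimated correlation camera called 0 of them (adjusted p from 0.545 to 0.728), and fry called 7.

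In Karpas-231 fold changes fell with GC content, by 0.41 on the log2 scale per 10 points of GC. With the GC offset 77.87% of the Karpas-231 calls that were tested again kept their direction and call, and with the GC and length offset 78%, which argues against either bias as the whole cause. Of the calls for the difference between lines 59.27% and 61.47% were kept. The tilt without treatment reached 0.2518 between the replicates of SC1 T and at most 0.06 in size between those of the other groups, and SC1 T against C had a tilt of 0.02. A tilt between libraries that arose without treatment and one that came with the drug cannot be told apart for this trend, since 1 replicate pair had a tilt over 0.5 of that size and the labels give no batch. SC1 C against Karpas-231 C had a tilt of -0.46 and SC1 T against Karpas-231 T one of -0.03, so the Karpas-231 C libraries may be those that stand apart.

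More genes were detected in T than in C of both lines. With libraries thinned to 1 total, the smallest gap between any T and any C library was 961 genes in SC1 and 1580 in Karpas-231, which argues against depth. Of 1575 long genes with no count in any C library, 80% in Karpas-231 and 81.0% in SC1 stayed at 0 in both T libraries, which argues against an even background of genomic reads. Of protein-coding genes at 0 in 1 thinned C library, at least 3.045 times as many reached 3 counts in a T library as in the other C library of the line, which argues against chance low values in C. A rise of some silent genes under a histone deacetylase inhibitor may be a candidate explanation, as a hypothesis, and RNA from other cells stays open.

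The germinal centre and B cell receptor signalling lists had a higher response in SC1. Both were still called with the GC offset (higher adjusted p = 0.0001998) and with each library left out in turn (highest adjusted p = 0.002703, without SC1 C replicate 2). These values argue against a GC tilt or a single library as the cause. With an estimated correlation neither was called, and fry did not call the germinal centre list (0.0511). A difference in biology between the lines may explain the pattern, as a hypothesis found and tested on the same libraries.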

How the results depend on the processing

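The GC offset, the GC and length offset, the restriction to genes with a GC value and that to protein-coding genes were chosen after seeing the data. Of 165 results for named genes, 142 kept call and direction in all settings run and 23 did not, and with the GC offset 158 of 163 did. Across settings 3004 single values for named genes kept their call and 96 lost it, and for called lists 791 kept it, 120 lost it and 1 turned. The list of the unfolded protein and amino acid response turned in SC1 without SC1 C replicate 1 (adjusted p = 0.838, against 2.54e-13 without SC1 C replicate 2). Library totals alone gave 619 genes lower in SC1 (945 in the fit reported) and 305 lower in both lines (573). No low-count filter gave 1595 lower in SC1, 79 at least 2-fold lower (39), a lower response in SC1 for 1538 (828), and a correlation of 0.194 (0.42), with 27468 genes tested. The stricter filter, with 10799 genes, gave 1308 at least 2-fold higher in Karpas-231 (2157), 622 lower in SC1, 22 at least 2-fold lower and 357 lower in both. Fits of only the libraries compared, with fewer samples, gave 1112 higher (1835), 331 lower and 21 at least 2-fold lower in SC1, 247 lower in both and a correlation of 0.495. Libraries that share a replicate number had deviations that correlated at 0.007 between C and T in Karpas-231 and 0.27 in SC1, and from -0.02 to 0.045 across lines, which leaves open whether numbers pair libraries in SC1. The replicate block gave 1507 lower and 61 at least 2-fold lower in SC1, a lower response in SC1 for 1323, 917 lower in both, and 7867 genes called in Karpas-231 and 3996 in SC1. An adjusted p below 0.01 left 2247 higher in Karpas-231 (3372), 1006 higher, 276 lower, 805 at least 2-fold higher (1294) and 16 at least 2-fold lower in SC1, responses higher for 845 (1758) and lower for 345, and 585 higher (1103) and 175 lower in both. Camera with an estimated correlation called 0 lists in Karpas-231 (14), 0 in SC1 (22) and 0 for the difference (12), where fry called 11, 17 and 7 of them. Over the 13476 genes with a GC value, where no offset gave 1398 at least 2-fold lower in Karpas-231 and 588 lower in both, the GC offset gave 877 and 978, and the GC and length offset 866 and 1040. With 1 library left out in turn, its lone partner assumed to vary like the other groups, genes lower in Karpas-231 numbered 2062 to 3792. In SC1 they numbered 1108 to 1751 higher, 567 to 884 lower and 830 to 1326 at least 2-fold higher, each lowest without SC1 C replicate 2. At least 2-fold lower were 35 to 109. Responses higher in SC1 numbered 636 to 2103, and lower 482 to 961. Genes lower in both numbered 306 to 654. The correlation was 0.322 to 0.392. Lists called numbered 11 to 16, 19 to 23 and 10 to 14. Unless fewer genes or samples were tested or the threshold was stricter, the cause was not tested. Folds of genes below 0.105 to 0.179 CPM by library totals, 3 counts in a library, were not given.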

Other observations

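The lists, genes and starting-level test of this part were chosen after the results were seen. Adjusted p of these lists is over them alone, not over 31. The other histone cluster genes fell in Karpas-231. Of 58 tested members 37 fell, 3 rose and 18 were not called (camera adjusted p = 2.17e-12, 0.168 with an estimated correlation). They were not called as a list in SC1 (adjusted p = 0.564), and the test of the difference gave adjusted p = 3.45e-11, or 0.255 with an estimated correlation. The small RNA share given in the report also fell in Karpas-231 alone, and the selection of RNA was not excluded as a cause. Tubulin genes differed between the lines as well (adjusted p = 2.34e-06, 0.255 with an estimated correlation). In Karpas-231 7 of 16 tested members fell, 3 rose and 6 were not called (camera adjusted p = 0.00106, 0.177 with an estimated correlation), and the call was lost with the GC and length offset (0.0649). TUBB fell from 3512 ± 276 to 1219 ± 45.1 CPM and TUBA1B fell from 4180 ± 401 to 1832 ± 86.8 CPM there. Among immunoglobulin constant and IGLL genes in Karpas-231, 4 of 10 tested members fell, 0 rose and 6 were not called (camera adjusted p = 0.000363, 0.116 with an estimated correlation), and this call too was lost with the GC and length offset (0.0649). IGHG1 fell from 215 ± 18.5 to 56.0 ± 6.07 CPM and IGHM fell from 2086 ± 168 to 774 ± 7.80 CPM, n = 2 libraries per group.

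Integrin and adhesion genes rose as a list in both lines. In Karpas-231 14 of 28 tested members rose, 1 fell and 13 were not called (camera adjusted p = 0.000303, 0.116 with an estimated correlation). In SC1 11 rose, 1 fell and 16 were not called (camera adjusted p = 2.60e-06, 0.0746 with an estimated correlation). ITGAV, an integrin subunit, rose from 14.1 ± 0.261 to 41.7 ± 4.40 CPM in Karpas-231 and from 0.314 ± 0.0817 to 1.66 ± 0.302 CPM in SC1. ITGB1, its partner, rose from 43.2 ± 2.71 to 118 ± 17.9 CPM and from 175 ± 47.8 to 316 ± 4.98 CPM. Genes of the germline did so too. In Karpas-231 8 of 16 tested members rose, 1 fell and 7 were not called (camera adjusted p = 0.00158, 0.116 with an estimated correlation). In SC1 8 rose, 0 fell and 8 were not called (camera adjusted p = 0.000142, 0.0746 with an estimated correlation). TEX19 rose from 1.59 ± 0.00780 to 39.9 ± 8.12 CPM in Karpas-231 and from 0.469 ± 0.0595 to 4.76 ± 0.659 CPM in SC1. For these lists the lines were not shown to differ (adjusted p = 0.51 for integrins and 0.128 for the germline). Chemokine and chemokine receptor genes rose in SC1. There 4 of 13 tested members rose, 0 fell and 9 were not called (camera adjusted p = 8.30e-06, 0.0746 with an estimated correlation). In Karpas-231 5 rose and 1 fell, and the list was not called (adjusted p = 0.134), nor for the difference (0.065). CXCR5, which guides B cells to follicles, rose from 35.8 ± 6.96 to 106 ± 18.1 CPM in SC1. It rose more in Karpas-231 (log2 fold change 2.75 against 1.56).

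As a hypothesis, a gene that starts lower in 1 line may rise more there under the drug. To keep chance values apart, the start was taken from replicate 1 of C and the response against replicate 2 of C, with the GC trend removed. Across 13476 genes, which are not independent replicates, the difference in start and the difference in response between lines had an r of -0.245, and -0.259 with the replicates exchanged. Without its removal these were -0.295 and -0.307 over the same genes. C enters both differences with opposite sign, so a negative r cannot decide the hypothesis. Anything shared by both C libraries of a line would act alike and stays open.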
